A study of Gallus gallus with 18 samples.

How the data were processed

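Total RNA from the uterus of Hy-Line Brown hens was isolated with Trizol and made into libraries with an Illumina TruSeq RNA kit, per the labels' protocols. Each of the 18 libraries was put in its group by the strength group and calcification period in its labels. The labels number the libraries 1 to 3 within a group. They say that samples came from hens but do not tie each library to a separate hen, so p-values measure the spread between these samples, which may in part be technical.

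The authors deposited a table of counts per gene for all libraries and a table of read statistics. The submitters' processing notes name Bowtie2, TopHat, TopHat2 and the genome build galGal4, without versions. The counting tool, its strand setting and the annotation release are not given in the sources used here, so counts of paralogs, overlapping genes and antisense genes are uncertain. The gene table is named as normalized, but its values were treated as counts because none of the deposited values was fractional, no whole number from 0 to 15 was missing in any library, and the totals followed the number of clean read pairs (Pearson's r = 0.950 over 18 libraries, as a check of the unit). A scaling by factors close to 1 followed by rounding would be hard to see in such values. In the read statistics, the authors gave read counts before and after their filter and the percent of bases at quality 30 and of GC, of which the values of mate 1 were used.

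The table holds 20866 loci, 17108 with Ensembl identifiers and 3758 numbered by the authors outside that annotation; 1117 had no counts in any library. The RefSeq gene table of assembly GRCg7b used here had 0 rows with an Ensembl identifier, so identifiers could not be matched to it. The files do not pair identifiers with names. The 27 gene lists fixed by symbol before the data were examined were therefore not tested, and no marker of another cell type was examined. Totals ranged from 13322102 to 16125109 counts per library, and 3 counts, used as the floor for a gene at 0, correspond to between 0.186 and 0.225 CPM before scaling. This floor covers counting error only. Pairs of libraries within a group differed by more than counting noise, with a chi-square per degree of freedom of 8.60 to 318, so no pair was counted as 1 library deposited again. This does not show that they came from separate hens.

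Genes above 1 CPM in at least 3 libraries were kept, 16110 in all. Counts were scaled with TMM factors and tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3) by the quasi-likelihood test in a model with a mean for each of the 6 groups over all 18 libraries. Contrasts were high minus low strength within each period and averaged over periods, and differences between periods averaged over the strength groups. An F test of 2 contrasts asked whether the strength difference changed with the period. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes within a comparison, with a threshold of 0.05. Standard errors were the log2 change divided by the square root of the F statistic. Principal components and correlations between libraries used log2 CPM with a prior count of 2. Tables were handled in Python 3.11.15 with pandas 2.3.3, and exact permutation tests of read statistics used scipy 1.17.1.

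The planned rule for naming genes took the 10 largest rises and 10 largest falls past the threshold with a symbol, a mean of at least 1 CPM in the higher group and, for strength within a period, no overlap between groups, plus fixed symbols and members of the gene lists. Without symbols, the rule was applied to Ensembl identifiers and shortened to 2 rises and 2 falls per comparison, a change made when values could already be seen. Novel02327 was added as the only call in growth.

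The following alternatives were planned before the data were examined. These were DESeq2 1.42.0 with its own size factors, no filter on low counts, the replicate number as a block, limma-voom with library quality weights, leaving out each library in turn, and a fit to the 6 libraries of 1 period. Total-count and upper-quartile scaling, fits to 1 strength group and the termination fit without high termination replicate 3 were added after seeing the data. Other pseudocounts and quantile normalization were planned for normalized values and did not apply to counts.

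The test was run on simulated data with 100 genes changed 2-fold and 100 changed 4-fold among 16110. At initiation it called 18 and 61 of these, in growth 14 and 60, at termination 18 and 68, and averaged over periods 61 and 92. For growth against initiation it called 37 and 78, for termination against growth 35 and 87, and for termination against initiation 42 and 81. No call had the wrong sign, between 1 and 10 unchanged genes were called, and 0 genes were called in each comparison when nothing was changed. Each gene was drawn on its own, with the same spread in every library. No simulated library therefore departed from its group across many genes, as high termination replicate 3 did. The rates of false calls need not hold for the real libraries.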

Results

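The uterus of the laying hen, also called the shell gland, is the part of the oviduct in which the egg receives its calcified shell. RNA was sequenced from uterus samples of Hy-Line Brown hens, a commercial layer, at 42 weeks of age. The labels place 18 libraries in 6 groups of 3, from 2 eggshell strength groups (high and low) at 3 calcification periods (initiation, growth and termination). The libraries held between 13322102 and 16125109 counts. Each library had counts for 17663 to 18217 of the 20866 loci listed, and 16110 loci were abundant enough to test. The files give Ensembl identifiers without gene names, so genes are named here by identifier.

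The main axis of variation set the growth libraries apart from those of initiation and of low strength termination. The first principal component of log2 CPM (counts scaled to library size) held 53.7% of the variance, and the 6 growth libraries scored between 73.6 and 93.6 on it. The 6 initiation libraries scored between −87.1 and −15.4. The low strength termination libraries scored −48.4, −120 and −103. The high strength termination libraries did not lie together. Replicates 1 and 2 scored 73.0 and 89.5, beside the growth libraries, and replicate 3 scored −108, beside the low strength termination libraries. Pairs of libraries within the high termination group correlated across genes at Pearson's r between 0.794 and 0.966, against 0.933 to 0.990 within the other 5 groups.

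**Figure D1:**
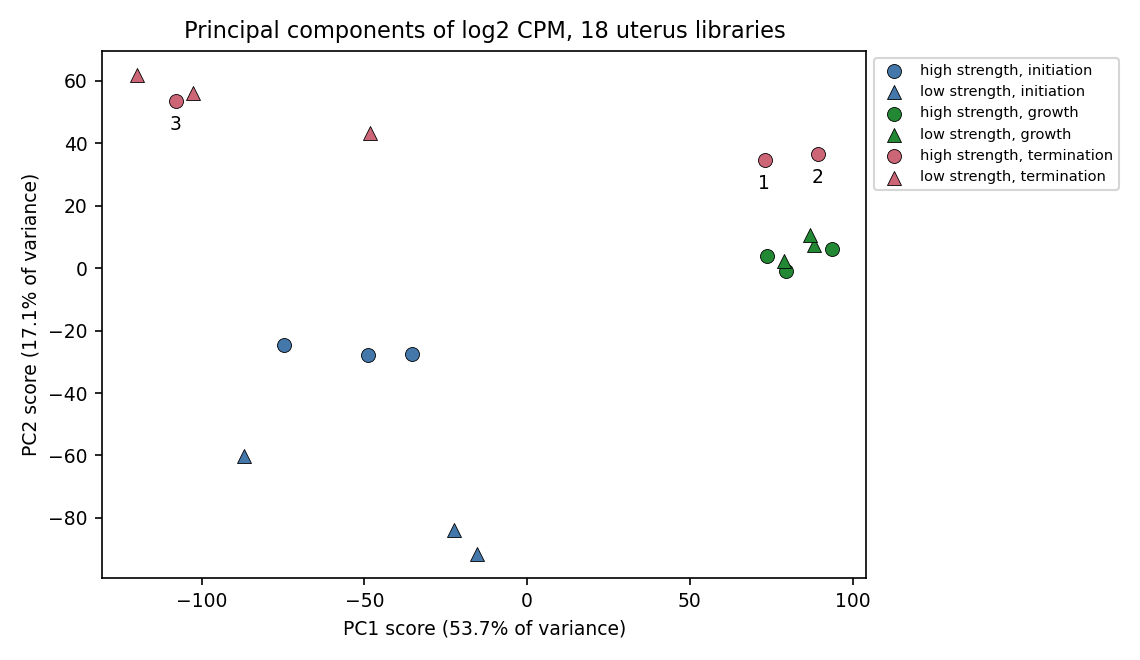
Scores of the 18 libraries on principal components 1 and 2 of log2 CPM, with the percent of variance on each axis; colour gives the period, circles the high and triangles the low strength group, and digits number the high termination replicates. High termination replicates 1 and 2 scored 73.0 and 89.5 on the first component and replicate 3 scored −108.

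The first question concerned how uterine expression changed as calcification went from initiation to growth. In growth, 4358 genes were higher and 4613 lower than at initiation, averaged over the strength groups, which is 55.7% of those tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). More than 2-fold changes were estimated for 4883 of the called genes. ENSGALG00000006413 rose from 0.644 ± 0.498 CPM in high initiation to 157 ± 83.5 CPM in high growth (SD, n = 3), and from 0.133 ± 0.118 to 166 ± 79.5 CPM in the low strength groups. Its log2 change was 9.01 with a standard error of 1.11 (edgeR adjusted p = 3.14e-05). ENSGALG00000020984 had no counts in any of the 6 initiation libraries and reached 5.50 ± 0.833 CPM in high growth and 5.68 ± 1.34 CPM in low growth, at least 29.2-fold above a floor of 3 counts per library (edgeR adjusted p = 8.90e-05). Among genes that fell, ENSGALG00000015134 stood at 4.56 ± 5.22 CPM in high initiation and 48.2 ± 33.1 CPM in low initiation, and at 0.131 ± 0.227 and 0.0804 ± 0.0315 CPM in growth, a log2 change of −7.06 with a standard error of 1.84 (edgeR adjusted p = 0.00556). ENSGALG00000015261 was also called lower in growth, where it had 1 count in all 6 libraries, but its level at initiation came from the low strength group alone, at 285 ± 25.3 CPM against 0.416 ± 0.720 CPM in the high strength group.

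Much of the change from initiation to growth was shared by the strength groups, while for 307 genes the change differed between them (670 without high termination replicate 3). Within the high strength group 2990 genes rose and 2555 fell, and within the low strength group 2388 rose and 2353 fell. Of the genes that rose in the high strength group, 1602 also rose in the low strength group, where independent lists of these sizes would share 443. Of those that fell, 1060 fell in both, where independent lists would share 373. Only 40 genes rose in the high strength group and fell in the low one, and 11 did the reverse. The fold changes of both groups, which have no library in common, correlated across genes at Pearson's r = 0.702 and Spearman's rho = 0.753; genes are not independent replicates. Of the 3383 tested loci that the authors numbered outside the Ensembl annotation, 603 rose and 1243 fell, a split that was not tested against that of Ensembl genes. With scaling to total counts the share of called genes that rose was 38.5%, against 48.6% with scaling by trimmed mean of M values (TMM), and the median log2 change of all genes moved to −0.14.

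**Figure D2:**
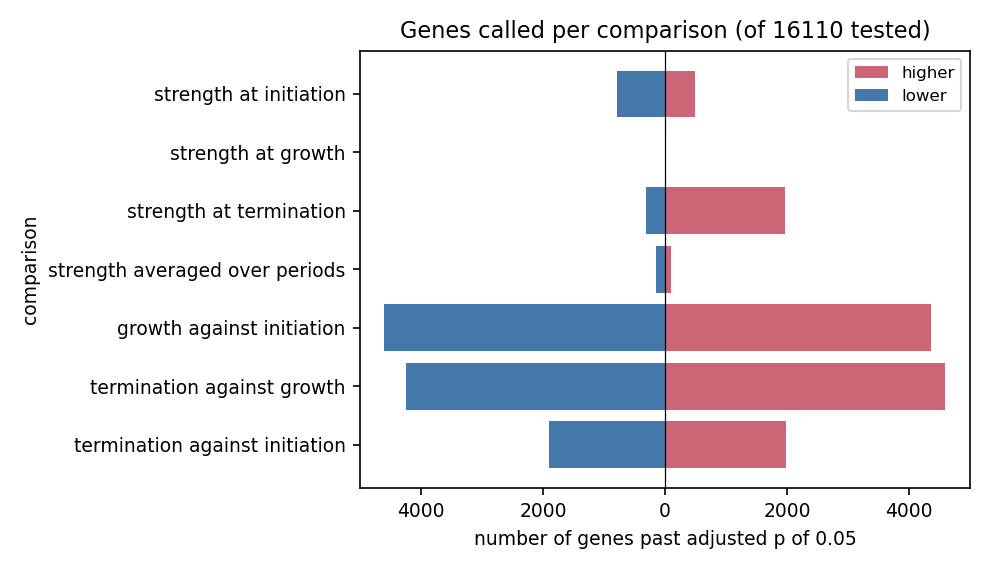
Number of genes with an edgeR adjusted p below 0.05 in each comparison, of 16110 tested, with genes that were lower drawn to the left of 0 and higher to the right; strength comparisons are high against low strength. Growth against initiation called 4358 higher and 4613 lower, and strength at growth called 1.

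From growth to termination, 4598 genes rose and 4247 fell (edgeR quasi-likelihood test). ENSGALG00000010169 fell from 7.23 ± 1.22 CPM in high growth and 8.47 ± 2.46 CPM in low growth to 1.98 ± 1.86 CPM in high termination and to 0 counts in the 3 low termination libraries (edgeR adjusted p = 9.03e-04). ENSGALG00000000803 fell from 1.39 ± 0.306 CPM in high growth and 1.31 ± 0.524 CPM in low growth to a total of 2 counts in all 6 termination libraries (edgeR adjusted p = 1.52e-04). The genes with the largest estimated rises drew much of their level from 1 library. ENSGALG00000015134 was at 516 CPM in high termination replicate 3, at 0.272 and 0.0626 CPM in replicates 1 and 2, and at 27.0 ± 17.5 CPM in low termination (edgeR adjusted p = 0.00174). ENSGALG00000019845 had 54.9 CPM in high termination replicate 3, 0 and 0.125 CPM in replicates 1 and 2, and 4.0 ± 2.74 CPM in low termination (edgeR adjusted p = 0.00307).

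Far more genes passed the test from growth to termination in the low strength group, where 4391 rose and 4487 fell, than in the high strength group, where 743 rose and 491 fell. The difference between the strength groups in this change passed the test for 4 genes, and for 6991 genes without high termination replicate 3. Of the 743 that rose in the high strength group, 598 also rose in the low strength group, where independent lists would share 203, and 364 of the 491 that fell in the high group also fell in the low group, where independent lists would share 137. Many genes that growth had raised in one strength group were lowered by termination in the other. Of the 2990 genes that rose from initiation to growth in the high strength group, 2296 fell from growth to termination in the low strength group, which is 76.8% against 833 expected of independent lists. Of the 2555 that fell, 1525 rose again, against 696 expected. Of the 3383 tested loci outside the Ensembl annotation, 1240 rose and 486 fell, again not tested against Ensembl genes. With total-count scaling the share of called genes that rose was 30.9%, against 52.0% with TMM, and the median log2 change of all genes moved to −0.28.

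Termination against initiation gave 1993 genes that were higher and 1907 that were lower (edgeR quasi-likelihood test). ENSGALG00000001866 rose at each step, from 0.633 ± 0.248 CPM in high initiation through 15.3 ± 9.80 CPM in high growth to 134 ± 71.9 CPM in high termination, and from 0.455 ± 0.223 through 19.5 ± 11.2 to 280 ± 33.1 CPM in the low strength groups. Its log2 change from initiation to termination was 8.49 with a standard error of 0.56 (edgeR adjusted p = 8.81e-08). ENSGALG00000009877 was at 0.110 ± 0.0313 CPM in high initiation and 0.104 ± 0.0929 CPM in low initiation, and at 6.90 ± 2.89 CPM in low termination (log2 change 7.28, standard error 0.82, edgeR adjusted p = 1.23e-05). In high termination it ranged from 2.14 CPM in replicate 3 to 100 CPM in replicate 2. Among genes that were lower, ENSGALG00000009382 fell from 9.47 ± 1.04 CPM in high initiation and 148 ± 27.1 CPM in low initiation to 0.443 ± 0.150 and 0.0926 ± 0.0892 CPM (log2 change −7.49, standard error 0.48, edgeR adjusted p = 7.00e-08). ENSGALG00000015261 had no counts in the 6 termination libraries, at least 603-fold below its mean at initiation, which the low strength group supplied; neither this call nor the one in growth held without high initiation replicate 1.

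Across all genes, the differences between termination and initiation in the high and low strength groups correlated weakly, at Pearson's r = 0.182 and Spearman's rho = 0.0271. The genes called in both groups nevertheless mostly moved the same way. Of these, 581 were higher at termination in both groups and 437 lower in both, where independent lists would share 214 and 155. In opposite directions, 14 were higher in the low and lower in the high strength group, against 131 expected, and 105 were lower in the low and higher in the high group, against 254 expected. The change differed between the strength groups for 2446 genes, a count that single libraries moved to between 413 (without low initiation replicate 1) and 8491 (without high termination replicate 3). With total-count scaling 5956 genes were called and 16.8% of these were higher, against 3900 and 51.1% with TMM; the median log2 change of all genes moved to −0.34.

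The series was designed to compare hens laying hard and weak shells within each period. At initiation, 489 genes were higher and 795 lower in the high strength group (edgeR quasi-likelihood test), and 963 of these were estimated to differ more than 2-fold. The largest fall was in ENSGALG00000005360, which reached 10702 ± 1894 CPM in low initiation and 0.449 ± 0.295 CPM in high initiation (SD, n = 3). Its log2 difference, high minus low, was −14.52 with a standard error of 0.88 (edgeR adjusted p = 2.23e-07), and its mean in the other 4 groups lay between 0.375 and 1.61 CPM. ENSGALG00000016012 had 15.3 ± 6.68 CPM in low initiation and no counts in high initiation, at least 76.1-fold lower (edgeR adjusted p = 3.27e-04). In the other direction, ENSGALG00000013568 was at 64.2 ± 52.6 CPM in high initiation and 4.69 ± 1.33 CPM in low initiation (log2 difference 3.77, standard error 0.52, edgeR adjusted p = 4.04e-04). ENSGALG00000017813 was at 8.88, 0.508 and 3.33 CPM in the high initiation libraries and at 0.0827 ± 0.0438 CPM in low initiation (log2 difference 5.57, standard error 1.47, edgeR adjusted p = 0.0299).

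**Figure D3:**
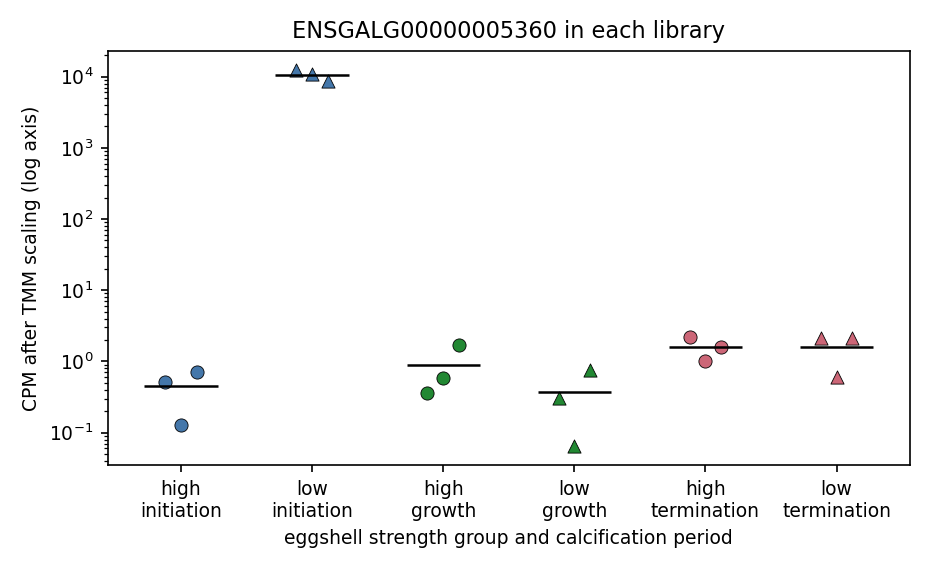
CPM of ENSGALG00000005360 after TMM scaling, on a log axis, in each library of the 6 groups; circles are high and triangles low strength libraries, colours are periods, and the line is the mean of 3. The gene averaged 10702 CPM in low initiation and no more than 1.61 CPM in any other group.

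The low initiation libraries also had a higher share of sequenced bases at quality 30 or above, 94.7% ± 0.445, than the high initiation libraries, 91.6% ± 0.0503 (exact two-sided permutation test, p = 0.1, the smallest that 3 against 3 libraries allow). The labels name no sequencing batch. The number of genes called at initiation was 815, 760 and 694 without high initiation replicates 1, 2 and 3, 552 and 663 without low initiation replicates 1 and 2, and 1327 without low initiation replicate 3. DESeq2 called 2076 genes and the edgeR test on the 6 initiation libraries alone called 2141.

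During growth the strength groups were hard to tell apart. edgeR's quasi-likelihood test called 1 of 16110 genes, DESeq2 called 11 genes and limma-voom with library weights called 5. An unadjusted edgeR p below 0.05 was found for 374 genes (2.32%). That is a smaller share than the 0.05 that unchanged genes would give on average under a well-set spread. The called locus, Novel02327, one that the authors numbered outside the Ensembl annotation, had 4.79 ± 1.29 CPM in high growth and 0.225 ± 0.0817 CPM in low growth (log2 difference 4.37, standard error 0.58, edgeR adjusted p = 0.0289), and was named after its value was seen. It lost the call without each of 5 of the 6 growth libraries, the exception being high growth replicate 3, and also with the replicate block and in the fit to the 6 growth libraries alone, each of which called 0 genes. The absolute log2 difference had a median of 0.13 and a 95th percentile of 0.81 over all genes, with a median standard error of 0.35. In simulated data of this design the test called 60 of 100 genes changed 4-fold and 14 of 100 changed 2-fold in growth. The simulation used the spread fitted over all 6 groups. The median SD of log2 CPM per gene was 0.266 in high growth, 0.213 in low growth and 0.606 in high termination. A shared spread above that of the growth libraries would make the test too strict in growth, which was not tested. These simulated rates need not be those of the growth libraries.

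At termination, 1971 genes were higher and 309 lower in the high strength group (edgeR quasi-likelihood test). Those higher were mostly genes that growth had raised over initiation in other libraries: 1606 of the 1971, or 81.5%, were among the 4358 that rose from initiation to growth, where independent lists would share 533. Of the 309 that were lower, 182 had fallen from initiation to growth, against 88.5 expected. ENSGALG00000028048 showed this pattern, with 187 ± 65.6 and 292 ± 80.6 CPM in high and low growth, 106, 102 and 1.74 CPM in high termination replicates 1, 2 and 3, and 1.19 ± 0.386 CPM in low termination (log2 difference 5.88, standard error 1.02, edgeR adjusted p = 0.0271). ENSGALG00000023475 had 3.60, 2.94 and 0.0793 CPM in the high termination libraries and 1 count in all low termination libraries (edgeR adjusted p = 0.0271). Lower in the high strength group were ENSGALG00000017813, at 0.269 ± 0.109 against 4.59 ± 0.866 CPM (log2 difference −4.03, standard error 1.29, edgeR adjusted p = 0.0492), and ENSGALG00000022250, with 3 counts in all high termination libraries against 1.63 ± 1.16 CPM (edgeR adjusted p = 0.0436). The strength difference of ENSGALG00000017813 changed with the period (edgeR adjusted p = 0.0285), but its call at initiation was lost in 5 of 13 alternatives and that at termination in 8 of 13. The termination calls of ENSGALG00000028048 and ENSGALG00000023475 were each lost in 5 of 13 alternatives and that of ENSGALG00000022250 in 7 of 13.

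On a scale through the 8971 genes called between initiation and growth, with 0 at the mean initiation library and 1 at the mean growth library, high termination replicates 1, 2 and 3 stood at 0.905, 1.04 and −0.0435. The low termination libraries stood at 0.259, −0.0625 and 0.00102. The count at termination depended on single libraries. It was 9234 without high termination replicate 3 (4664 higher and 4570 lower), 2 and 15 without replicates 1 and 2 of that group, 3605 without low termination replicate 1, and 2 without low termination replicate 2 and also without replicate 3. The test on the 6 termination libraries alone called 0 genes, and 5669 genes had an unadjusted p below 0.05 in the fit to all libraries. DESeq2 called 3861. The fit to all libraries shared the spread of a gene over all groups. The median SD of log2 CPM per gene was 0.606 in high and 0.333 in low termination. It was 0.213 to 0.270 in the other groups. The adjusted p-values at termination thus rest on a spread taken in part from groups that varied less, and may be too small.

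**Figure D4:**
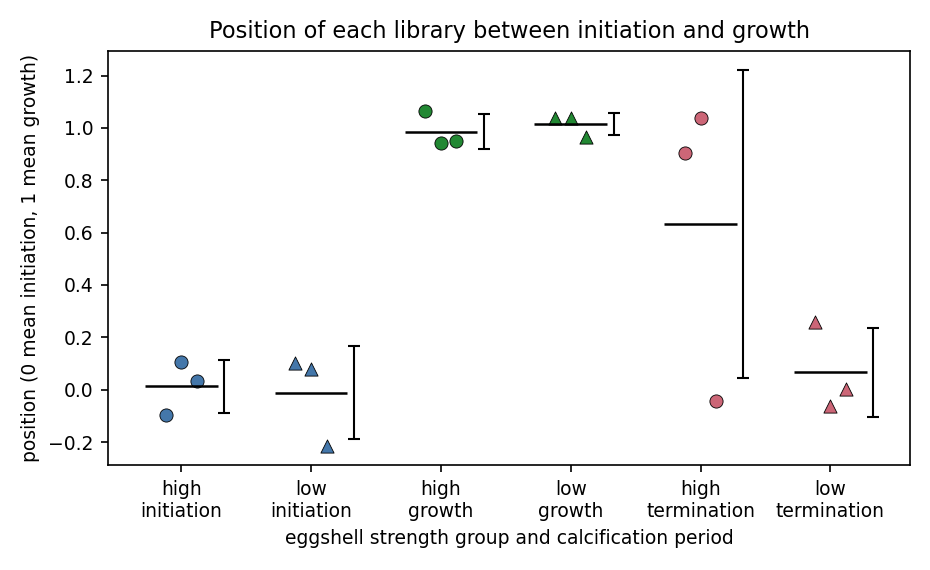
Position of each library on a scale with 0 at the mean initiation and 1 at the mean growth library, over genes called between these periods; circles are high and triangles low strength libraries, lines are means and bars SD of 3. Initiation and growth libraries define the scale, and high termination libraries stood at 0.905, 1.04 and −0.0435.

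Averaged over the periods, 105 genes were higher and 155 lower in the high strength group (edgeR quasi-likelihood test). ENSGALG00000014965 was higher in the high strength group in each period, at 4.63 ± 2.72 against 0.549 ± 0.196 CPM at initiation, 11.2 ± 2.73 against 4.55 ± 3.09 CPM in growth and 5.59 ± 5.23 against 1.01 ± 0.340 CPM at termination (log2 difference 2.28, standard error 0.38, edgeR adjusted p = 0.00800). ENSGALG00000009639 had 87.4 ± 48.8 against 14.5 ± 4.44 CPM at initiation, 40.4 ± 40.7 against 8.0 ± 3.87 CPM in growth and 8.94 ± 5.41 against 4.66 ± 1.38 CPM at termination (log2 difference 1.95, standard error 0.44, edgeR adjusted p = 0.0389). The call of ENSGALG00000009639 was lost in 16 of 24 alternatives, among them the replicate block and leaving out each of 15 single libraries. The largest falls came from initiation alone. ENSGALG00000005360 had a mean log2 difference of −4.44 (standard error 0.44, edgeR adjusted p = 1.05e-04), and ENSGALG00000008848 had 29.9 ± 7.77 CPM in low initiation and at most 0.0798 CPM on average elsewhere (log2 difference −4.25, standard error 0.93, edgeR adjusted p = 0.0389); the latter call was lost in 13 of 24 alternatives, among them the replicate block and total-count scaling. The calls numbered 4840 without high termination replicate 3 and fell to between 97 and 152 without high initiation replicate 2 or 3, high growth replicate 3, high termination replicate 1, low initiation replicate 1 or 2, low growth replicate 2 or 3, or low termination replicate 2 or 3. Higher genes were 40.4% of the calls with TMM, 52.8% with total-count scaling and 55.7% with DESeq2.

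The strength difference changed with the period for 943 genes (edgeR quasi-likelihood F test of 2 interaction contrasts). Between initiation and termination it changed for 2446 genes, more positive at termination for 1835 and more negative for 611. That count was 413 to 1330 without each of the initiation and termination libraries other than low initiation replicate 3 (3562), low termination replicate 1 (3385) and high termination replicate 3 (8491). The excess of positive changes was nearly absent without high termination replicate 3, with 4354 more positive and 4137 more negative. With limma-voom library weights the numbers were 5941 and 5890, and with total-count scaling 2684 and 381. In every other alternative more changes were positive than negative, among them DESeq2 with 2761 and 1228. Between initiation and growth the strength difference changed for 307 genes. That count was 126 to 211 without each of the initiation and growth libraries other than low initiation replicate 3 (358), and 670 without high termination replicate 3. It was 794 with DESeq2, 4860 with limma-voom library weights and 285 with the replicate block. Between growth and termination the strength difference changed for 4 genes, with 0 to 5 without each library other than high termination replicate 3 (6991). DESeq2 called 548 genes here, limma-voom with library weights 9503 and the fit with the replicate block 0. ENSGALG00000005360, with its level in low initiation alone, was among the 943 (edgeR adjusted p = 2.62e-06). Across genes the strength differences at initiation and termination correlated at Pearson's r = −0.128 and Spearman's rho = −0.222, and few genes were called in both periods. Higher in the high strength group in both were 26 genes, against 59.8 for independent lists, and lower in both were 24, against 15.2. Higher at initiation and lower at termination were 13, against 9.38, and the reverse held for 52, against 97.3. The count of 943 was between 234 and 593 without each of the other 15 libraries in turn, 1322 without low termination replicate 1, 1766 without low initiation replicate 3 and 8526 without high termination replicate 3. With the replicate number as a block it was 577.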

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

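The tests of shared labels, stage, sequencing quality, scaling and single libraries, and those of other splits of the libraries, were chosen after the results had been seen; those on abundant genes and on other tissue were written down before their results.

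The fit called genes whose difference between strength groups changed with the period. The interaction test passed for 943 genes, and the strength difference changed for 307 genes between initiation and growth, 4 between growth and termination and 2446 between initiation and termination (edgeR quasi-likelihood test). Among the genes named above, the change of the strength difference with the period had an edgeR adjusted p of 2.62e-06 for ENSGALG00000005360, 0.000713 for ENSGALG00000009382, 0.00929 for Novel02327, 0.0105 for ENSGALG00000028048, 0.0119 for ENSGALG00000013568, 0.0170 for ENSGALG00000016012, 0.0285 for ENSGALG00000017813 and 0.0438 for ENSGALG00000023475. Of 100 splits of the libraries, 15 gave an interaction count as high as 943, the real one included, and the highest other split gave 8505, so chance is not excluded; a count that far above the real one points to a structure of the libraries that the groups do not follow.

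High termination replicate 3 lay apart from replicates 1 and 2 and next to the low termination libraries. A swap of labels with a library of another period is argued against. Of the 15 libraries outside the group, 0 correlated best with a group of another period. A swap with a low termination library would keep the period, so this count could not show it. The partner in such a swap would resemble high termination replicates 1 and 2. The low termination libraries correlated with these at r from 0.768 to 0.886, and with each other at 0.933 to 0.978. These values argue against such a swap as the reason that replicate 3 lay apart. Abundant genes are argued against as well: without the 20 genes that were among the 10 most abundant in a library, the lowest r of replicate 3 with a low termination library still exceeded its highest r with replicates 1 and 2 by 0.136. A single wrong label with no partner stays open, because the mean r of replicate 3 with the low termination libraries, 0.962, is above the lowest r among these, 0.933. Wrong labels on replicates 1 and 2 stay open too and were not tested. Replicate 1 correlated best with low growth (mean r 0.940) and replicate 2 with high growth (mean r 0.953). Only replicate 3 of this group correlated best with a termination group. Sampling of the hens of this group at different points between growth and termination stays open too. A scale was set with 0 at low growth and 1 at low termination. It used 5868 genes called between these groups but not between low initiation and low growth. Replicates 1, 2 and 3 stood at 0.132, 0.0591 and 1.05 on it. The high growth libraries reached up to 0.0607 (SD 0.0425), so replicate 1 lay above them and replicate 2 did not. Initiation libraries stood at 0.214 to 0.672, so a place above growth on this scale is not particular to termination. On the second principal component replicates 1 and 2 scored 34.6 and 36.6. Growth libraries scored −0.943 to 10.8 on it and low termination libraries 43.4 to 62.0.

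At termination 86.4% of the calls were higher in the high strength group. This 86.4% was found with the median gene at a log2 difference of −0.0040, but that value comes from the main scaling and is no test of it. The share was 81.6% with upper-quartile scaling, where the median gene stood at −0.076. It was 94.0% with total-count scaling (3083 higher and 196 lower), where the median gene stood at 0.26. The choice among these scalings is therefore argued against as the cause. The asymmetry was absent with limma-voom library weights, which called 5612 higher and 5647 lower (49.8% higher). Among fits that left out 1 termination library, only that without low termination replicate 1 kept the asymmetry (81.4% higher). Without high termination replicate 1 or 2, or low termination replicate 2 or 3, only 2 to 15 genes were called. Those are too few to show an asymmetry. The asymmetry also depended on high termination replicate 3 being in the fit. Without it 50.5% of the calls were higher, and 52.1% in the fit to the other termination libraries alone. Higher calls rose from 1971 to 4664 as lower calls rose from 309 to 4570, so the library did not produce the higher calls. Why its presence held back lower calls more was not tested. An effect of shell strength on this asymmetry was not tested apart from these libraries.

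Genes present in low initiation and nearly absent elsewhere formed a set of 24, with at least 10 CPM there and 20 times the highest other group mean, limits set after the data were seen. A trend with the share of bases at quality 30 is argued against as the sole cause: over the 35 genes, these 24 among them, that pass the same limits between the initiation groups alone, it would place low growth at 0.712 of the way from high to low initiation on the log2 scale, and the 3 low growth libraries stood at a median of 0.00611 ± 0.0106 (mean ± SD). RNA of another tissue or cell type in these libraries could keep the genes in 1 ratio, and the SD of their log2 ratios between libraries, 0.394, was below the median of 0.472 for genes of like level but at the 17.8th percentile of 1000 draws, which decides nothing. A batch of preparation or sequencing particular to the low initiation libraries cannot be told apart from the group, because the labels name no batch. Low shell strength itself stays open as a biological explanation that was not tested.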

How the results depend on the processing

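Total-count and upper-quartile scaling and the fits to 1 strength group were chosen after seeing the data. Period comparisons kept their counts of calls within 1.5 times when 1 library of the compared groups was left out. The counts for strength did not. The cause of the changes below was not tested. limma-voom with library quality weights called 9900 genes for strength at initiation, 5 in growth, 11259 at termination, 8596 averaged over periods, 9101 for termination against initiation and 12973 for the interaction. DESeq2 called 2076, 11 and 3861 for strength at initiation, growth and termination, 1001 averaged over periods and 3360 for the interaction. Fitted to the 6 libraries of a period, the test called 2141 at initiation, 0 in growth and 0 at termination, and 7074 at termination without high termination replicate 3. The high and low strength groups alone gave 5545 and 4741 genes for growth against initiation, 1234 and 8878 for termination against growth, and 3586 and 3386 for termination against initiation. Total-count scaling called 5956 for termination against initiation, and it moved the median log2 difference at termination to 0.26; upper-quartile scaling moved that of growth against initiation to −0.14.

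Only libraries of the groups compared were left out in turn, although the spread was shared over all 18 libraries. Leaving out 1 of these gave 552 to 1327 genes for strength at initiation, 0 to 1 in growth and 2 to 9234 at termination. It gave 97 to 4840 averaged over periods and 234 to 8526 for the interaction. It gave 7382 to 8609 for growth against initiation, 7266 to 9506 for termination against growth and 3182 to 5705 for termination against initiation. Of 428 values of named genes under alternatives, 360 stayed past the threshold, 68 kept their direction but not the call and 0 reversed.

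The replicate numbers were not taken to pair the libraries: 11 of 45 same-number pairs had deviations correlated above 0.1, all 3 pairs did so for 1 of 15 pairs of groups (high termination with low initiation, r from 0.479 to 0.737), and 8 of 18 libraries correlated best with their own number. With the number as a block, the calls were 1262, 0 and 2023 for strength at initiation, growth and termination, 201 averaged over periods, 9062, 8901 and 3854 for the period comparisons and 577 for the interaction. Other pseudocounts, quantile normalization and the gene list alternatives were not run, since they did not apply to counts or needed symbols. Depth lay between 13322102 and 16125109 counts in all libraries, and no alternative depth was tried.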

Other observations

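The 24 genes nearly restricted to low initiation comprised 15 with Ensembl identifiers and 9 loci that the authors numbered. Together they took 1.66%, 1.43% and 1.15% of the scaled counts in the 3 low initiation libraries and at most 0.00958% in any of the other 15. ENSGALG00000005360 supplied 75.7% of that level. All 24 had counts in each low initiation library. By the same limits, 0 genes were restricted to any other single group, 0 to both growth groups, 0 to both initiation groups and 4 to both termination groups.

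The 10 most abundant genes took 16.9% ± 0.597 of the counts in high initiation and 12.2% ± 3.71 in low initiation. Their share was 16.2% ± 1.76 in high growth and 17.04% ± 1.40 in low growth (SD, n = 3), and 29.3% ± 3.60 in low termination. In high termination it was 14.2%, 15.9% and 24.8% in replicates 1, 2 and 3. The GC content of reads was 51.9% ± 1.22 in low termination and 49.7% ± 0.780 in low initiation.

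Other splits of the libraries gave a measure of how far each count stands from chance, with tests chosen after the counts were seen. For strength within a period there are 10 splits of the 6 libraries, too few for a share under 0.05. At initiation the real split called 1284 genes, the highest other split called 0, and 1 split was as high. In growth the real split called 1, the highest other called 2, and 3 splits were as high. At termination the real split called 2280, the highest other called 8451, and 2 splits were as high; the latter points to a structure of those libraries that the strength groups do not follow. For strength averaged over periods, 7 of 100 splits called at least 260 genes and the highest other called 5518, so chance is not excluded.

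For the period comparisons 1 of 100 splits, the real one, called as many genes, which is the smallest share that these splits allow. Growth against initiation called 8971 genes and the highest other split 1425. Termination against growth called 8845 and the highest other split 8686. Termination against initiation called 3900 and the highest other split 3307. In both comparisons with termination, a split other than the real one thus came close to the real count. Labels were drawn within each strength group, so a split can keep the real periods of 1 strength group and exchange libraries of the other. Low strength alone called 8878 genes for termination against growth. A close count thus need not mean a structure other than the period, and which libraries the close splits exchanged was not examined. Those counts do not tell the periods apart from other structure among these libraries.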
